A study of Mus musculus with 7 samples.

How the data were processed

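Gene expression was measured in 3T3-L1 cells, an established mouse line of fibroblast-like pre-adipocytes that fill with fat droplets when they are given a hormone mixture. Per the labels' protocols, differentiation was started with isobutylmethylxanthine, dexamethasone and insulin for 2 days and kept up with insulin alone. The cells received either a commercial inhibitor of stearoyl-CoA desaturase (SCD) at 1 µM or its solvent DMSO for the whole period, and total RNA was taken on day 7. SCD enzymes put the first double bond into saturated fatty acids. The compound is not named in the sources used here. Per the labels' protocols, 100 ng of RNA per sample was turned into biotin-labelled target for Affymetrix whole-transcript arrays, with 1 array per sample. The treatment label puts 4 arrays in the DMSO group and 3 in the SCD inhibitor group, 7 in all, and every column of the table matched 1 sample.

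The deposited values are expression levels on the log2 scale that were made with RMA, per the submitters' processing notes. RMA is a method that corrects the background, brings the arrays to a common distribution and summarises the probes of each transcript cluster. Its version, the array annotation release and any filter are not given in the sources used here. The log2 scale was read from the values, which ran from 2.23 to 13.2 with array medians between 4.88 and 4.94. The deposited values are stored coarsely: 100% of those of 8 and above lay on steps of 1/512. Of the 28996 transcript clusters, 645 had the same values as another one on every array. No array was identical to another. Scanner files and detection calls were not used here, so the number of arrays limits the precision and no statement is made on whether a dim gene was expressed.

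Transcript clusters were named from the array annotation. It gave 1 gene symbol to 21218 of them and several symbols to 1881, and 5897 were not listed there. Of those with 1 symbol, 21185 matched a mouse gene of RefSeq (assembly GRCm38.p6) through their Entrez number, and no symbol had to be updated. Clusters with several symbols or none were left out of the main comparison, since they name no single gene, and are counted in the closing section. Where a gene had more than 1 cluster, as 1386 genes did, the one with the highest mean over all arrays stood for it. This left 18820 genes, and no filter on dim genes was applied.

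All 7 arrays entered 1 linear model with a term for the inhibitor, fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3. The residual degrees of freedom were 5 and the prior degrees of freedom 1.68. P-values were adjusted over all 18820 genes by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Values are given as the difference in log2, inhibitor minus DMSO, with its standard error (SE), and as group means with their standard deviation (SD). RMA values can compress changes near both ends of the scale, so fold changes of very dim and very abundant genes may be understated to a degree that is not known.

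A set of 32 gene lists, covering lipid metabolism, adipocyte and precursor markers, stress responses and markers of other cell types, was fixed before the data were examined, together with the samples' groups, the test and the alternatives. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 32 lists. Camera was repeated with a correlation estimated for each list. The repeat rests on the 5 residual degrees of freedom, so a call lost there need not mean that the genes vary together. Limma's fry was run beside it: it asks whether the genes of a list move on balance in 1 direction, or in either direction, and compares the list with no other genes. Some genes stand in more than 1 list. For each list the members past the threshold were also counted with p adjusted over the list alone.

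Genes were named by a rule fixed at the same time: all measured SCD genes, all measured members of a set of core genes of fat synthesis and adipocyte identity whatever their result, the 12 called genes with the largest increase and the 12 with the largest decrease among those whose groups did not overlap, and up to 4 called members of each list with the largest change, or 2 members with the smallest p where a list had none. Predicted genes, RIKEN clones, small RNA genes and olfactory or vomeronasal receptors were counted but not named by it. The rule took 138 genes. From the genes the rule took, the text prints examples, mostly of those that kept their call in every fit without 1 array. The others it prints stand with their values in the fits that changed their call. Genes printed from outside the rule were chosen after their values were seen and are named as such at the end of the results and in the closing section.

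The alternatives were the replicate number as a block, a further quantile normalization, centring each array on its median, dropping the dimmest 25% or 50% of genes, a variance trend, robust eBayes, array weights, precision weights by level, testing every transcript cluster on its own, averaging a gene's clusters, a minimum change of 1.2-fold (limma's treat), an estimated correlation in camera, and leaving out each of the 7 arrays in turn. Leaving out both arrays numbered 1, those of lowest array weight in their groups (0.583 for DMSO 1 and 0.499 for SCD inhibitor 1), was added after seeing the data. All 35 splits of the arrays into 4 and 3 were fitted in the same way. Gene neighbours were taken from the order of genes in GRCm38.p6 and no coordinates are given. The test was checked on simulated data with the real means and spread of the 18820 genes of this comparison and 200 changed genes drawn from those above the median level. It recovered 74.2% of genes changed by 0.3 in log2, 97.6% of those changed by 0.6 and 100% of those changed by 1, and 4.71% of its calls were false. The errors were drawn independently for each gene, so this does not check the test where genes vary together on an array. With 200 changed genes against 1505 called in the data, and no dim ones among them, these shares need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.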

Results

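Transcript levels were measured on 7 arrays of differentiated 3T3-L1 adipocytes, 4 from cultures kept in DMSO and 3 from cultures kept in 1 µM of an SCD inhibitor until day 7. The labels call the material pre-adipocytes and the series design calls it adipocytes. Arrays of the same group correlated at 0.99869 to 0.99946 over all genes (9 pairs) and arrays of different groups at 0.99711 to 0.99796 (12 pairs). The first principal component held 66.3% of the variance and placed all DMSO arrays on one side and all inhibitor arrays on the other. The number of arrays limits the precision, and the median standard error of a difference was 0.039 on the log2 scale. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

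The comparison asked which transcripts differ when stearoyl-CoA desaturase is inhibited throughout fat cell differentiation. With the inhibitor, genes of cholesterol synthesis and of the extracellular matrix rose, and target genes of the stress-induced transcription factor ATF4 fell. Tm7sf2, a sterol reductase of cholesterol synthesis, rose 2.36-fold (log2 1.24, SE 0.10, n = 3 against 4). Mmp14, a membrane-bound protease of the matrix, rose 1.72-fold (log2 0.78, SE 0.045). Trib3, a pseudokinase induced by ATF4, was 3.15-fold lower (log2 -1.66, SE 0.062). Pparg, the main regulator of fat cell differentiation (log2 0.07, SE 0.024), and Adipoq, which encodes adiponectin (log2 0.05, SE 0.026), did not pass the test. Adipoq lies at a mean level of 12.41, and no gene above 11.88 passed with a change over 0.5, so a change of it may be hidden. A smaller change did pass above 11.88, that of Gpd1 at 12.28, given below. Pck1, the cytosolic enzyme of glyceroneogenesis, was 4.24-fold lower (log2 -2.08, SE 0.052).

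In limma's fit, 1505 of 18820 genes (8.0%) passed an adjusted p of 0.05, 682 higher and 823 lower with the inhibitor. In all 1505 the inhibitor values lay wholly above or wholly below the DMSO values. Over all genes 17.3% were separated in this way, against 5.71% by chance. Most changes were small, with a median absolute log2 difference of 0.34 among called genes. Changes beyond 2-fold were found for 5 higher and 73 lower genes. Centring each array on its median turned the split to 1296 higher and 1030 lower, so that the lower share went from 54.7% to 44.3%. Leaving out SCD inhibitor 1 turned it likewise, to 712 higher and 582 lower, and a further quantile normalization gave 1032 of each. The total dropped to 980 without DMSO 4 and to 949 without SCD inhibitor 3. The number of higher genes was 423 without DMSO 3, 437 without DMSO 4, 369 without SCD inhibitor 2 and 408 without SCD inhibitor 3, and the number of lower genes was 543 without DMSO 4 and 541 without SCD inhibitor 3. Without both arrays numbered 1, a choice made after seeing the data, 808 genes passed, 434 higher and 374 lower.

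**Figure D1:**
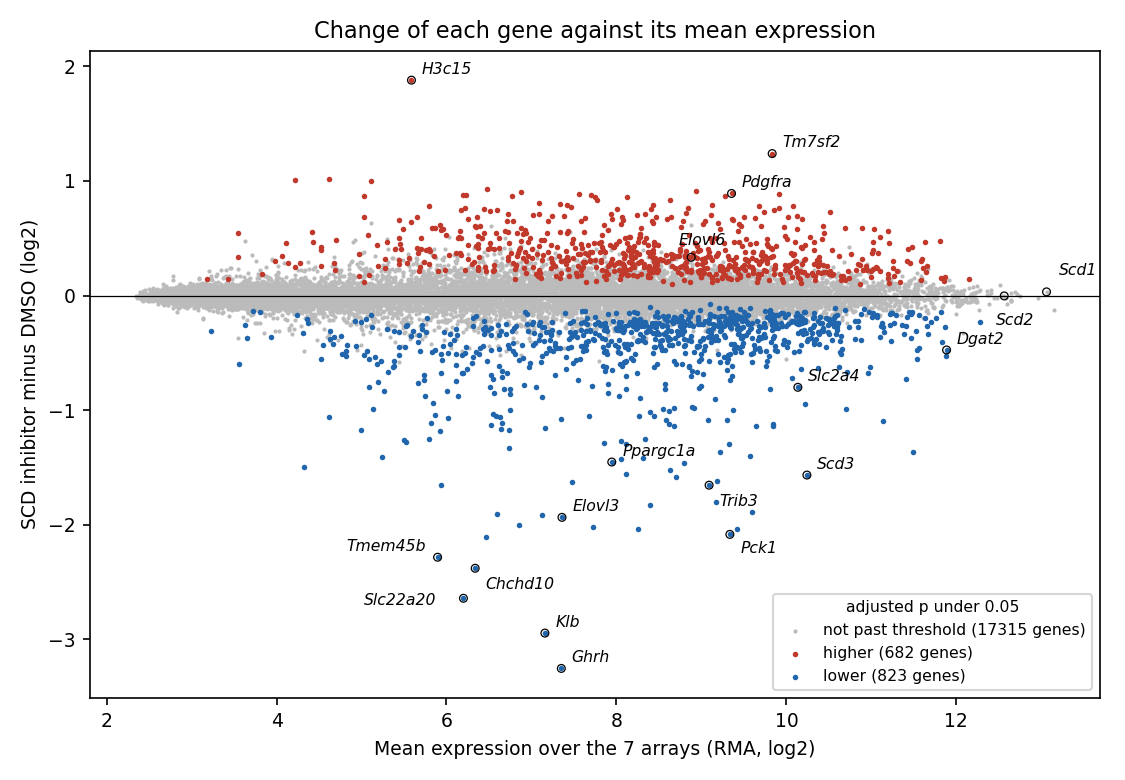
Each point is 1 of 18820 genes, with its mean expression over the 7 arrays (RMA, log2) on the horizontal axis and its difference, SCD inhibitor minus DMSO (log2), on the vertical axis. Red marks the 682 higher and blue the 823 lower genes past adjusted p 0.05 (limma); Scd1 and Scd2 lie at the upper end of the range near 0, and the largest decrease is that of Ghrh at -3.25.

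The transcript of the main desaturase gene of fat, Scd1, was at 13.05 ± 0.040 (SD, n = 4) in DMSO and 13.08 ± 0.0059 (SD, n = 3) with the inhibitor, a difference of 0.03 that did not pass (adjusted p = 0.507 in limma, 95% interval -0.03 to 0.09). Scd2 likewise did not pass, at a log2 difference of -0.00 (SE 0.024). Scd1 ranked 2 and Scd2 ranked 13 of all genes by level, and none of the 13 genes at or above the level of Scd2 passed the test. Scd3 fell from 10.91 ± 0.073 to 9.35 ± 0.040, a 2.96-fold decrease (log2 -1.57, SE 0.043, adjusted p = 2.46e-05). Scd4 read 3.81 in DMSO and 3.82 with the inhibitor, near the lower end of the scale, and its log2 difference of 0.02 did not pass. Of the 4 SCD genes 1 passed, by adjustment over all genes and also adjusted over the list alone. The list had a median of 0.01, a mean of -0.38 and a downward camera direction that did not pass (adjusted p = 0.332).

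Among 17 genes of fatty acid elongation and of desaturation by other enzymes, 3 rose and 2 fell, and adjusted over the list alone 5 rose and 2 fell. Both front-end desaturases of polyunsaturated fatty acids rose, Fads2 by 0.48 (SE 0.022) and Fads1 by 0.42 (SE 0.030). Elovl6, which lengthens palmitate to stearate, rose by 0.33 (SE 0.048, adjusted p = 0.00832), a call that ended without both arrays numbered 1 (adjusted p = 0.0807 in limma). Elovl3, an elongase of very long fatty acids, was 3.83-fold lower (log2 -1.94). The list as a whole did not pass camera (adjusted p = 0.188); its median was 0.04, its mean -0.04 and its camera direction upward.

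In de novo lipogenesis, 5 of 14 measured genes fell and 2 rose, and adjusted over the list alone 8 fell and 3 rose. The decreases included Mid1ip1, a partner of acetyl-CoA carboxylase (from 9.80 ± 0.027 to 8.80 ± 0.051), Thrsp (log2 -0.73, SE 0.045) and Mlxipl (-0.76, SE 0.073), which encodes the carbohydrate-responsive factor ChREBP. Acaca, the cytosolic acetyl-CoA carboxylase, fell by 0.38 (SE 0.042, adjusted p = 0.0029). Fasn, the fatty acid synthase, was at 11.77 ± 0.053 in DMSO and 11.50 ± 0.10 with the inhibitor and fell by 0.27 (adjusted p = 0.0262), but its adjusted p in limma was 0.0832 without DMSO 1, 0.0767 without DMSO 2, 0.0559 without DMSO 3, 0.0666 without DMSO 4 and 0.0541 without SCD inhibitor 1. Acss2, which makes acetyl-CoA from acetate, and Acly, which makes it from citrate, rose by 0.73 (SE 0.063) and 0.22 (SE 0.034). Srebf1, whose product drives fatty acid synthesis genes, did not pass (log2 0.15, adjusted p = 0.085 in limma); it did without DMSO 1 (adjusted p = 0.00494), without both arrays numbered 1 (0.0231), with array weights (0.0288) and when the dimmest 50% of genes were dropped (0.0439). Camera placed the list lower (adjusted p = 0.00403), with adjusted p = 0.239 with an estimated correlation.

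Of 17 genes of triacylglycerol synthesis 5 fell, the same number adjusted over the list alone, and 12 did not pass. Dgat2, an enzyme of the last step of triacylglycerol synthesis, fell by 0.47 (SE 0.026, adjusted p = 1.47e-04), and Agpat5, a lysophosphatidate acyltransferase, fell by 0.47 (SE 0.061). Dgat1, which catalyses the same step as Dgat2, had a log2 difference of 0.05, and Gpam, Agpat2 and Lpin1 had differences of -0.05, 0.07 and -0.17, none of them past the test. Camera placed the list lower (adjusted p = 0.00878), with adjusted p = 0.239 with an estimated correlation, and the call ended when the dimmer 50% of genes were dropped (adjusted p = 0.0512). Of 11 lipolysis genes 5 fell and 6 did not pass; adjusted over the list alone 6 fell. They included Ces1d (-1.14, SE 0.050) and Ces1f (-0.61, SE 0.037), carboxylesterases, and G0s2 (-0.46, SE 0.017), an inhibitor of adipose triglyceride lipase. The main lipases did not pass: Pnpla2 had a log2 difference of -0.03 and Lipe one of -0.07. Agpat2, Pnpla2 and Lipe lie at mean levels of 12.15, 12.17 and 12.07, where a change may be hidden, since no gene above 11.88 passed with a change over 0.5. Smaller changes did pass there: Dgat2 fell from 12.09 in DMSO, and Gpd1 of the triacylglycerol list (log2 -0.23) has a mean level of 12.28. The call of Gpd1 ended without DMSO 4 (adjusted p = 0.05 in limma), SCD inhibitor 2 (0.0578) or SCD inhibitor 3 (0.0602). The lipolysis list was lower in camera (adjusted p = 7.66e-06), with adjusted p = 0.116 with an estimated correlation.

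Lipid droplet proteins did not pass as a list (adjusted p = 0.263 in camera): 4 of 16 rose and 1 fell, 5 and 2 adjusted over the list alone. Plin4, a droplet coat protein, rose by 0.31, but its adjusted p in limma was 0.0559 without DMSO 2, 0.0563 without DMSO 3, 0.0604 without DMSO 4 and 0.0626 without SCD inhibitor 3. Among 18 genes of fatty acid uptake, binding and activation 2 rose and 1 fell, the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.189 in camera). The fatty acid transporter Cd36 (log2 -0.04), the binding protein Fabp4 (0.04) and lipoprotein lipase Lpl (0.01) did not pass. Their mean levels of 11.94, 12.36 and 12.71 lie above 11.88, the highest at which a gene passed with a change over 0.5. A change of them may thus be hidden, though Gpd1 passed with a smaller change at 12.28. Acsl4, an acyl-CoA synthetase of arachidonate, fell by 0.36, with adjusted p = 0.0517 without DMSO 4 and 0.0614 without SCD inhibitor 3 in limma.

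**Figure D2:**
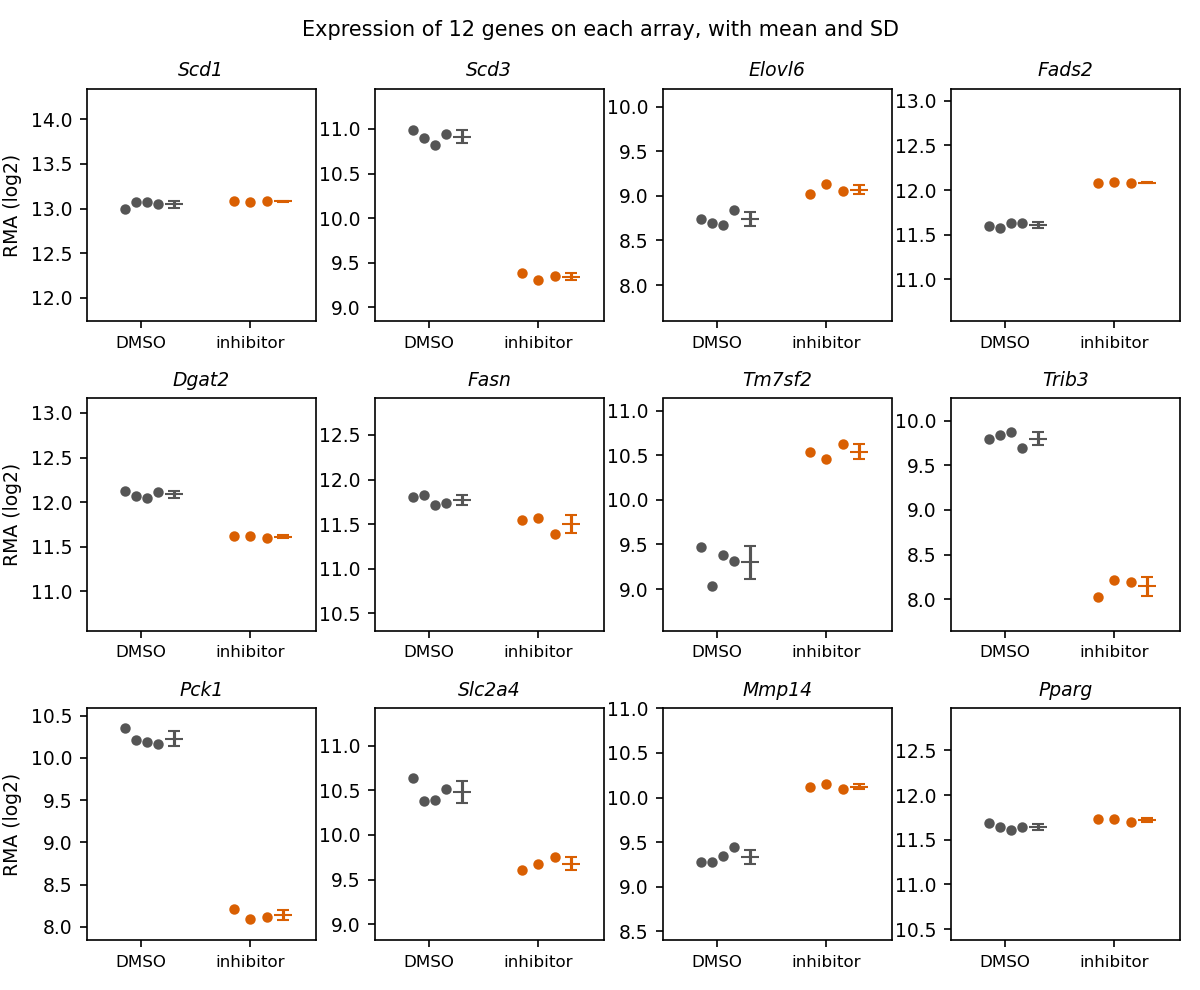
Expression (RMA, log2) of 12 genes on each of the 4 DMSO arrays (grey) and 3 SCD inhibitor arrays (orange), with the mean and SD of each group beside the points. The vertical scale differs between panels; Scd3, Trib3 and Pck1 lie lower on every inhibitor array than on any DMSO array, and Scd1 and Pparg differ by 0.03 and 0.07.

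Cholesterol synthesis and SREBP2 targets rose: 13 of 20 measured genes were higher and 7 did not pass, and adjusted over the list alone 17 rose and 1 fell. Beside Tm7sf2, the increases included Pmvk (0.72, SE 0.047), phosphomevalonate kinase, Stard4 (0.71, SE 0.039), a cholesterol carrier, and Dhcr7 (0.59, SE 0.053), a late enzyme of the pathway. Sqle (-0.10) and Cyp51 (-0.11), also enzymes of this pathway, did not pass over all genes. The list was higher in camera (adjusted p = 2.36e-13, and adjusted p = 0.0225 with an estimated correlation). Among 11 LXR targets 2 fell, the cholesterol exporter Abcg1 by 0.51 (SE 0.029) and Mylip, an E3 ubiquitin ligase, by 0.27 (SE 0.038); adjusted over the list alone 3 fell and 2 rose, and the list did not pass (adjusted p = 0.107 in camera). Of 28 phospholipid genes 1 rose and 1 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.375 in camera). Of 24 sphingolipid genes 1 rose and 3 fell (2 and 5 adjusted over the list alone) with no call for the list (adjusted p = 0.438 in camera). Sphk1, which makes sphingosine 1-phosphate, rose by 0.43 (SE 0.044).

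Genes of the ATF4 and integrated stress response fell broadly: 17 of 21 were lower and 4 did not pass, and adjusted over the list alone 18 fell. After Trib3, the decreases were largest for Ppp1r15a (-0.99, SE 0.035), which feeds back on the response through eIF2α dephosphorylation, and Chac1 (-0.79, SE 0.028), which degrades glutathione. Slc7a11, the cystine transporter, fell by 0.64 (SE 0.12), though its adjusted p in limma was 0.079 without DMSO 2, 0.0787 without DMSO 3, 0.0844 without DMSO 4 and 0.0898 without SCD inhibitor 2. The list was lower in camera (adjusted p = 1.5e-16, and adjusted p = 0.014 with an estimated correlation). Chaperones and other genes of the unfolded protein response did not pass as a list (adjusted p = 0.217 in camera): 3 of 21 rose and 2 fell, or 4 and 3 adjusted over the list alone. Of 22 genes of the NRF2 and oxidative stress response 6 fell and 16 did not pass, while adjusted over the list alone 10 fell and 5 rose; the list did not pass (adjusted p = 0.107 in camera) except without both arrays numbered 1 (adjusted p = 0.0495). Gsta3, a glutathione transferase, fell by 1.05 (SE 0.083), and Hmox1, haem oxygenase, fell by 0.27 (SE 0.039).

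Of 21 white adipocyte markers 4 fell and 17 did not pass, with the same count adjusted over the list alone. The 4 were Pck1, Trarg1 (-1.40, SE 0.033), a regulator of glucose transporter traffic, Slc2a4 (-0.80, SE 0.070, adjusted p = 0.00112), which encodes the insulin-responsive glucose transporter, and the transcription factor Klf15 (-0.65, SE 0.035). Cebpa had a log2 difference of -0.01. The list did not pass camera (adjusted p = 0.103) with all arrays and did in 2 of 18 alternatives, without SCD inhibitor 1 (adjusted p = 0.0221) and with the arrays centred (adjusted p = 0.0349); adjusted p = 0.449 with an estimated correlation. Of 16 brown and beige markers 4 fell and 12 did not pass; adjusted over the list alone 5 fell. The coactivator Ppargc1a was 2.74-fold lower (log2 -1.45, SE 0.075), Cox8b 1.92-fold and Cox7a1 1.84-fold lower, both subunits of cytochrome c oxidase, and Ucp1 did not pass (-0.01). Cox7a1 lost its call without both arrays numbered 1 (adjusted p = 0.0818 in limma) and with the replicate number as a block (0.0834). This list was lower in camera (adjusted p = 0.00507), with adjusted p = 0.116 with an estimated correlation. Of 15 adipokines 5 fell and 1 rose (6 and 1 adjusted over the list alone), among them Nrg4 (-1.25, SE 0.070), Apln (-1.14, SE 0.083) and Lcn2 (-1.10, SE 0.058). The adipokine list was lower (adjusted p = 0.00878 in camera), with adjusted p = 0.284 with an estimated correlation, and did not pass without SCD inhibitor 3 (adjusted p = 0.0532).

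Glycolysis and glucose uptake genes fell in 4 of 19 cases and rose in 1, also adjusted over the list alone. Pfkp, a phosphofructokinase, fell by 0.81 (SE 0.041). The list was lower in camera (adjusted p = 0.0409), with adjusted p = 0.239 with an estimated correlation, and lost its call without SCD inhibitor 2 (adjusted p = 0.0948), without SCD inhibitor 3 (adjusted p = 0.0617) after a further quantile normalization (adjusted p = 0.0707) and when the dimmest 25% (adjusted p = 0.0674) or 50% (adjusted p = 0.144) of genes were dropped. Of 18 insulin signalling genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone. Igfbp4, a binding protein of insulin-like growth factors, fell by 0.32 (SE 0.036). The insulin signalling list did not pass (adjusted p = 0.107 in camera) except without SCD inhibitor 1 (adjusted p = 0.0459) and without both arrays numbered 1 (adjusted p = 0.0476).

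In mitochondrial fatty acid oxidation 5 of 19 genes fell and 1 rose; adjusted over the list alone 9 fell and 2 rose. Slc25a20, the carnitine carrier, fell by 0.36 (SE 0.048) and the thioesterase Acot2 by 0.39 (SE 0.044), while Cpt1a, which starts the import of fatty acids into mitochondria, rose by 0.43 (SE 0.034, adjusted p = 7.6e-04). The list was lower (adjusted p = 0.00155 in camera), with adjusted p = 0.239 with an estimated correlation. Of 17 peroxisomal genes 3 fell and 1 rose (6 and 1 adjusted over the list alone). Acox2, an oxidase of branched fatty acids and bile acid intermediates, was 4.07-fold lower and Ehhadh 2.66-fold lower. The peroxisomal list was lower (adjusted p = 0.0409 in camera), with adjusted p = 0.375 with an estimated correlation. It passed in 12 of 18 alternatives (adjusted p from 0.0146 to 0.21) and lost its call with the replicate number as a block (0.0644), without DMSO 2 (adjusted p = 0.0787), DMSO 4 (0.0693) or SCD inhibitor 3 (0.0793) and when the dimmest 25% (0.0686) or 50% (0.21) of genes were dropped. None of 32 oxidative phosphorylation genes passed in limma, over all genes or adjusted over the list alone; at an unadjusted p under 0.05, 2 were higher and 2 lower. Of these genes, Ndufa4 (log2 0.20) passed with the arrays centred (adjusted p = 0.0338). That list had a median of -0.00057, a mean of 0.0018 and an upward camera direction (adjusted p = 0.817). Of 18 genes of the tricarboxylic acid cycle 1 fell, also adjusted over the list alone: Pdhb, a subunit of pyruvate dehydrogenase, by 0.28, with adjusted p in limma of 0.0786 without DMSO 2, 0.0677 without DMSO 3, 0.0873 without DMSO 4, 0.0964 without SCD inhibitor 1 and 0.11 without SCD inhibitor 3. The cycle list was lower (adjusted p = 0.00878 in camera), with adjusted p = 0.379 with an estimated correlation.

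Extracellular matrix genes rose in 15 of 29 cases and 14 did not pass; adjusted over the list alone 18 rose. Beside Mmp14, the increases included the adhesion protein Thbs1 (0.60, SE 0.060), the proteoglycan Dcn (0.59, SE 0.059) and the gelatinase Mmp2 (0.58, SE 0.043), and among fibrillar collagens Col3a1 (0.50) and Col1a1 (0.41). The list was higher in camera (adjusted p = 9.13e-14, and adjusted p = 0.0189 with an estimated correlation). Markers of preadipocytes and fibroblasts moved with it: 6 of 20 rose and 1 fell, 8 and 1 adjusted over the list alone, with a median of 0.08. The growth factor receptors Pdgfra (0.89, SE 0.093) and Pdgfrb (0.51, SE 0.068) and the calcium-binding S100a4 (0.88, SE 0.10) rose, and the matrix gene Fn1 fell by 0.26 (SE 0.037). This list was higher (adjusted p = 0.0031 in camera), with adjusted p = 0.239 with an estimated correlation. Of 25 inflammation genes 7 rose and 1 fell (9 and 2 adjusted over the list alone), with increases of the chemokine Cxcl12 (0.53, SE 0.063) and the adhesion molecule Vcam1 (0.50, SE 0.061) against the decrease of Lcn2. The inflammation list was higher (adjusted p = 0.0151 in camera), with adjusted p = 0.239 with an estimated correlation, and lost its call without SCD inhibitor 1 (adjusted p = 0.0996) and without both arrays numbered 1 (adjusted p = 0.125).

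In the interferon list 2 of 21 genes rose, 3 adjusted over the list alone, led by Usp18 (0.59, SE 0.081), which removes the ubiquitin-like ISG15. The list did not pass (adjusted p = 0.114 in camera) except without DMSO 4 (adjusted p = 0.0495). Of 24 cell cycle genes 1 rose, the G1 cyclin Ccnd1 (0.47, SE 0.059), and 1 fell, Ccne1 (-0.19, SE 0.027); adjusted over the list alone 1 rose and 2 fell (list adjusted p = 0.217 in camera). Of 17 eicosanoid genes 4 fell and 1 rose, also adjusted over the list alone, with Cbr3, a carbonyl reductase, lower by a log2 difference of -0.58, a call lost without both arrays numbered 1 (adjusted p = 0.0537 in limma) and with the replicate number as a block (0.0561). The gene that rose was Cbr2, another carbonyl reductase (0.30). The eicosanoid list narrowly missed the threshold (adjusted p = 0.0553 in camera) and passed it in 9 of 18 alternatives (adjusted p from 0.0305 to 0.161), with adjusted p = 0.239 with an estimated correlation. Among these were the fits without DMSO 1 (0.0478), DMSO 2 (0.0441) or SCD inhibitor 1 (0.0464). Markers of other cell types were included as well. None of 12 macrophage and leukocyte markers and none of 9 endothelial markers passed in limma, also adjusted over the list alone, with 1 of the former and 0 of the latter at an unadjusted p under 0.05 (camera adjusted p = 0.686 and 0.817). The macrophage gene Lyz2 (log2 -0.33) passed with the arrays centred (adjusted p = 0.0452). Of 13 muscle, bone and cartilage markers 2 fell, also adjusted over the list alone: Alpl, a phosphatase of mineralising cells that adipocytes also express, by 1.42 (SE 0.063), and Des, the intermediate filament of muscle, by 0.98 (SE 0.056). This list did not pass (adjusted p = 0.106 in camera) except when the dimmest 50% of genes were dropped (adjusted p = 0.0279).

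**Figure D3:**
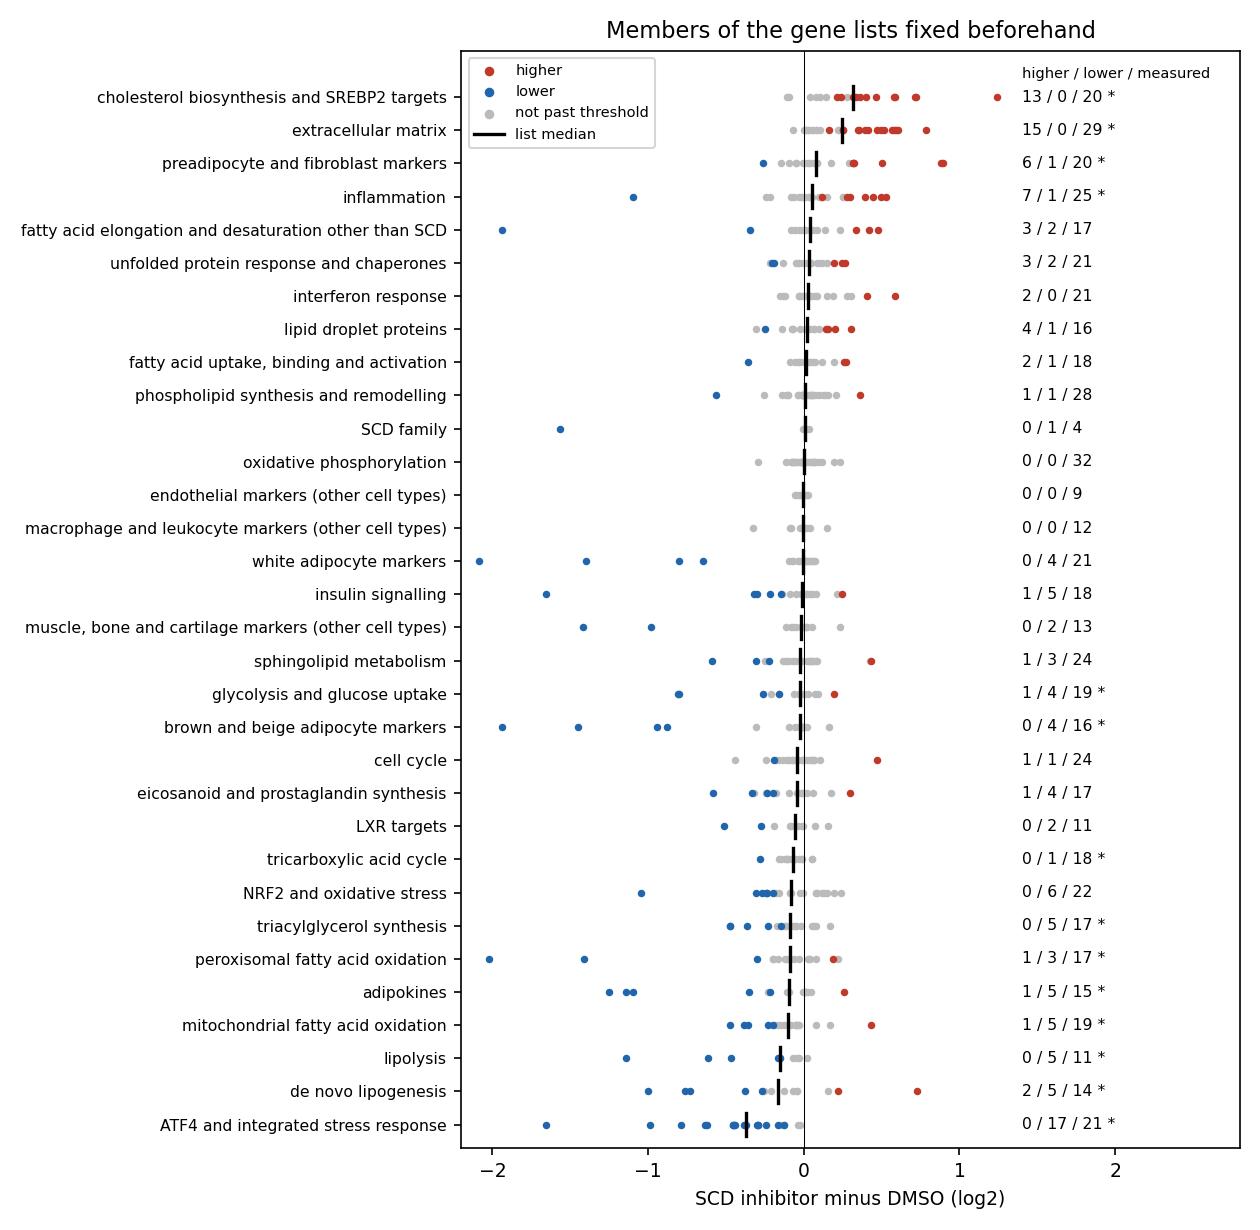
Log2 difference, SCD inhibitor minus DMSO, of every measured member of the 32 gene lists, with 1 point per gene (red higher, blue lower, grey not past adjusted p 0.05 over all genes) and a black bar at each list's median. The numbers at the right give members higher, lower and measured, and a star marks the 14 lists past adjusted p 0.05 in camera, of which 4 were higher and 10 lower; cholesterol genes lie highest and ATF4 targets lowest.

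The largest decreases were those of Ghrh, which encodes growth hormone-releasing hormone, 9.54-fold lower (log2 -3.25, SE 0.11, adjusted p = 3.61e-05 in limma), and Klb, the coreceptor for FGF21, 7.71-fold lower (-2.95, SE 0.13). Beside Pck1, Acox2 and Elovl3, they were followed by Slc22a20, an organic anion transporter (-2.64), Chchd10, a mitochondrial protein (-2.38), Tmem45b (-2.28), Slc25a34, a mitochondrial carrier (-2.11), Itih4 (-2.04), Tspan18 (-2.00) and the monooxygenase Fmo1 (-1.92). The largest increase was that of H3c15, a replication-dependent histone, from 4.78 ± 0.29 to 6.66 ± 0.40 (log2 1.88, SE 0.23, adjusted p = 0.00436), and the linker histone H1f3 rose by 0.90 (SE 0.11). Another transcript cluster, which carries H3c15 among several histone symbols and was left out of the comparison, rose by only 0.29 (SE 0.048). Ifi205 (1.02), the RNA sensor Tlr8 (1.00) and the integrin ligand Edil3 (1.00) roughly doubled from DMSO levels of 4.18, 3.79 and 4.69, toward the lower end of the scale. Casp12, a caspase of the endoplasmic reticulum (0.93), the prostaglandin F receptor gene Ptgfr (0.91), the matrix protease Adamts1 (0.89) and Ddah2 (0.88) also rose.

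Of the 32 lists, 14 passed camera and 3 did so with an estimated correlation, those of cholesterol synthesis, the extracellular matrix and ATF4. By fry, 20 lists moved on balance in 1 direction and 30 changed in either direction. Among the genes printed above, Acly, Sqle, Cyp51, Ucp1, Col3a1, Col1a1 and Fn1 were chosen after their values were seen.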

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

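The comparison of each DMSO array with the other 3 and the test of transcript clusters without a single symbol followed rules set in advance; no test was added here after a result was seen. In 11 of the 138 named genes, 1 DMSO array lay far from the other 3, by the ratio of its gap to the nearest array over the range of all 4 against Dixon's 95% critical value. Chance puts about 1 in 20 groups beyond this value, or 6.9 of 138 here. The inhibitor group of 3 was not tested in this way.

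In 8 of the 11 genes the far array was DMSO 1. Scd2 read 12.62 in DMSO 1 against 12.54 to 12.55 in the others (ratio 0.9231), Gpam 10.19 against 10.04 to 10.06 (0.8919), Pnpla2 12.28 against 12.14 to 12.15 (0.9559), Fabp4 12.30 against 12.36 to 12.37 (0.8788), Ddah2 7.499 against 7.07 to 7.10 (0.9252) and Gsta3 6.83 against 7.08 to 7.12 (0.8741). In Scd4, at 3.80 against 3.81 for all others, the ratio was 1, and in Cdh5, at 3.92 against 3.90 for all others, it was 0.8545; both differences are tiny and near the lower end of the scale. In the remaining 3 genes the far array was DMSO 2: Chchd10 at 7.20 against 7.39 to 7.43 (0.834), Cd14 at 3.88 against 3.94 to 3.95 (0.838) and the endothelial marker Emcn at 3.63 against 3.71 to 3.72 (0.9076). Of these genes, Ddah2 was higher with the inhibitor and Chchd10 and Gsta3 lower, by differences of 0.88, -2.38 and -1.05 that exceed the gap of the far array.

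Transcript clusters without a single gene symbol, which the comparison left out, also changed. Of 7778 such clusters 185 passed adjusted p 0.05 in limma, 96 higher and 89 lower with the inhibitor. Of the 185, 77 carried several symbols, so that no single gene can be named for them.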

How the results depend on the processing

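Leaving out both arrays numbered 1 was chosen after seeing the data; all other alternatives were fixed beforehand. No named gene past the threshold reversed its direction, and no gene called both here and under an alternative changed sign. The balance of calls did turn: 823 lower against 682 higher became 1296 higher against 1030 lower with the arrays centred, 712 against 582 without SCD inhibitor 1 and 434 against 374 without both arrays numbered 1. Of the 116 named genes past the threshold, 60 stayed past it under all 19 alternatives run for single genes, and 2 (Ifi205 and Tlr8) under the 18 run for them, since they are among the dimmest 50%. Of the 116, 105 stayed past it under those of these alternatives that leave out no array and use no block; the minimum change was not run for single named genes. With the replicate number as a block, on 6 arrays since DMSO 4 has no partner, 896 genes passed, 437 higher and 459 lower, and 733 of the main calls were kept (48.7%); this fit has fewer arrays. Of the genes printed in the results, Mylip (adjusted p = 0.053 in limma), Acot2 (0.0705), Ccne1 (0.0556), H3c15 (0.0607), Edil3 (0.0595), Ddah2 (0.0779) and Slc7a11 (0.0584) lost their call there too, beside Cox7a1 and Cbr3. Whether the number pairs the arrays is not settled. Deviations of arrays with the same number correlated at 0.174, 0.138 and 0.0796. Those of arrays with different numbers correlated at -0.171 to -0.0076, except SCD inhibitor 2 with DMSO 4 (0.16), which was more than with DMSO 2. Deviations are taken from the group means, which by itself makes some of these correlations negative. A further quantile normalization gave 1032 higher genes, and centring the arrays on their medians gave 2326 genes; the median difference over all genes was -0.0037 as deposited, 0.00328 and 0.0114 under these scalings, and the cause was not tested. A minimum change of 1.2-fold left 246 genes, 80 higher and 166 lower, since it asks for more than any change. Without both arrays numbered 1, 808 genes passed, with fewer arrays, and 660 main calls were kept (43.85%). Calls lost there were those of Fasn (adjusted p = 0.138 in limma), Pdhb (0.101), Usp18 (0.0984), Slc25a20 (0.0932), Pdgfrb (0.0906), Hmox1 (0.079), H1f3 (0.0744), Slc7a11 (0.061), Vcam1 (0.0583), Ehhadh (0.0575), Dcn (0.0519) and Acsl4 (0.0507), beside Elovl6, Cox7a1 and Cbr3. Leaving out 1 array at a time gave 949 to 1294 genes, 369 to 712 higher and 541 to 643 lower, and 11 to 16 gene lists. With an estimated correlation 3 lists passed in place of 14. Camera then tests each list on the 5 residual degrees of freedom in place of a number set by the genes, which makes calls harder. The shares of this and of the correlation itself were not separated. For the brown and beige list (-0.0302) and the glycolysis list (0.00191) the estimate lay below the preset 0.01. A higher correlation between genes therefore does not explain the lost calls of these lists. For the lists, robust eBayes and the minimum change were not run. Signal over background was not measured, so the values do not tell how many dim genes were expressed; 1.1% of genes in the dimmer 50% were called against 18.1% in the most abundant 10%.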

Other observations

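The genes and gene families of this and the next paragraph were chosen after their values were seen, and those of this paragraph stand for no group. Hcar1, the lactate receptor gene, fell by 1.63 (SE 0.11, n = 3 against 4, adjusted p = 4.0e-04 in limma), Hcar2, whose product binds ketone bodies and niacin, by 0.70 and the long-chain fatty acid receptor gene Ffar4 by 0.69. C1qtnf12 fell by 1.42 and Angptl8, an inhibitor of lipoprotein lipase, by 1.13. Prodh of proline breakdown (-1.46), Hpd (-1.28) and Hgd (-0.61) of tyrosine breakdown and Dbt of branched-chain amino acid breakdown (-0.99) fell as well. The growth factor genes Hgf (0.80), Fgf10 (0.79), Fgf7 (0.70), Kitl (0.69) and Vegfd (0.67) rose, though 2 of 22 genes of the Fgf stem did so and the stem did not pass camera (adjusted p = 0.825). Osr1 (0.79) and Zfp521 (0.70), transcription factors of mesenchymal precursors, also rose.

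Genes were also grouped by the stem of their symbol and tested with camera. Of 470 stems with 6 or more genes 9 passed, and none kept its call with an estimated correlation (adjusted p = 0.999 for each). That repeat rests on 5 residual degrees of freedom and had little power over 470 stems, so it decides little about the 9. Of 22 clustered protocadherin genes of the Pcdhb stem 6 rose (adjusted p = 9.45e-05), such as Pcdhb9 (0.54), and of 18 Adamts matrix proteases 4 rose, with Adamts5 (0.65) and Adamts4 (0.55) beside Adamts1. The stem H, of histones and H2 histocompatibility genes, had 14 of 82 genes higher, such as H4c9 (0.74), and 1 lower. Small heat shock proteins fell in 3 of 7 cases, Hspb1 (-0.68), Hspb8 (-0.61) and Hspb6 (-0.58), and Gstm glutathione transferases in 2 of 6, led by Gstm7 (-0.81). The other stems that passed were Col (9 of 42 genes higher), Gas (3 of 9), Rps (1 of 35) and Kat (1 of 6), all in the upward direction; Kat did not pass with the arrays centred (adjusted p = 0.0688).

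The grouping itself was tested as planned beforehand on all 35 splits of the arrays into 4 and 3. The real split was the only 1 as large for all genes (1505 against 0 in the highest other) and for gene lists (14 against 11). The same held for higher genes (682 against 0) and lower genes (823 against 0), which are not separate tests. A share of 1 in 35 is the smallest that these splits can give. Every other split puts DMSO and inhibitor arrays together in a group, which widens the spread, so 0 calls there say little. The splits cannot tell an effect of the inhibitor from any other difference between the DMSO and inhibitor arrays. At an unadjusted p under 0.05 in limma, the real split had 4128 genes and the highest other 2047.

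A run of neighbouring genes around Mdm2 was lower with the inhibitor. It was found from these falls, so every test of it was chosen after it was seen. Only the criterion for the correlation within groups was set before the value of that test was seen. Of its 9 genes above the median level of all genes 7 fell, among them Nup107 (-1.80), Cpsf6 (-1.30), Mdm1 (-1.15), Yeats4 (-1.12) and Cpm (-1.08). Of 20 flanking genes above that level 2 fell. Mdm2 (-0.02) and Slc35e3 (-0.07), the most abundant of the run, did not pass. They lie at mean levels of 12.48 and 12.39, above 11.88, the highest at which a gene passed with a change over 0.5. A fall of these 2 may thus be hidden, though Gpd1 passed with a smaller change at 12.28. Within the run more abundant genes changed less (Spearman rho of level and log2 change 0.817, permutation p = 0.0108). An accidental run is unlikely if neighbouring genes change independently. The share of random gene orders with as large a median in any window of 7 genes was 0.000999, the smallest that 1000 random orders can give. This does not separate copy number from shared regulation. A window around Apoc1, Apoc2 and Apoc4 (median -0.81) also lay beyond the 95th percentile of random orders, 0.481, so neighbours may not change independently. For copies that vary from culture to culture, that criterion was met, since the run's genes varied together within groups (mean correlation 0.215, above 96.0% of 1964 random sets). However, the run's mean level ranged by at most 0.108 within a group, against a gap of 0.774 between the groups. Such copies, fewer copies of the segment in all inhibitor cultures and a response of each gene to the inhibitor (median -1.08) cannot be told apart, because copy number was not measured and the fall of 7 of 9 genes is what prompted the question.

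Scd3 fell while Scd1 and Scd2 did not pass, and the tests of this were chosen after the result was seen. The change of Scd3 was -1.57, and its 95% interval lay apart from those of the other two. A ceiling of the signal may hide a fall of Scd1 and Scd2: of the 13 genes at or above the level of Scd2, 0 passed with a change over 0.5 in limma, and the largest change among them was 0.13. With such a ceiling, Scd3 probes that read Scd1 or Scd2 RNA could show a fall that the probes of these genes do not. A fall of Scd3 alone, a ceiling and shared probes therefore cannot be told apart here.

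Adipocyte genes such as Slc2a4 fell while matrix genes rose, and the tests of this were chosen after the result was seen. A lower share of differentiated adipocytes would lower such markers together. Over 9 white adipocyte markers above the median level of all genes and no higher than 11.88, the median was -0.0965. The 4 of them that fell had a median of -1.10, while Adig (0.05) and Cebpa (-0.01), at levels of 10.18 and 10.26, did not pass. With 4 of the 9 known to fall, the median of the 9 had to belong to a marker that did not pass, so it decides nothing. The level readings of Adig and Cebpa argue only against a loss that lowers all 9 markers equally as the sole cause. A loss that lowers markers unequally was not tested. A smaller loss is not excluded, since the 4 were picked for falling and changes of the more abundant markers may be compressed. For the matrix genes, more undifferentiated cells cannot be told apart from a response of the cells to the inhibitor. The median of 20 preadipocyte and fibroblast markers was 0.0754, and Fn1 among them fell. Their list was higher in camera (adjusted p = 0.0031, and 0.239 with an estimated correlation). A response of these genes to the inhibitor within adipocytes is possible for the first group and remains a hypothesis.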
